A study of Mus musculus with 4 samples.

How the data were processed

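Poly(A)-selected RNA of isolated mouse islets was sequenced in 4 libraries, 2 of control islets and 2 of islets given cytoEV daily for 48 h. Per the labels' protocols, islets recovered overnight and were treated in RPMI medium with 11 mM glucose, and libraries were made from 200 ng of total RNA with a stranded mRNA kit. Whether the counting used the strand is not given in the sources used here. The submitters' processing notes name TopHat2 2.0.6, StringTie 2.1.3, R 3.6.1, edgeR 3.1.1 and the mm10 build, with no role or order.

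The authors deposited a single table of CPM values with 24421 rows, a gene symbol and a column per library. Each column sums to 1000000 CPM, so no composition factor is contained in the values. The table's 2 control columns carry a name that reads as control EV and the labels say untreated. They were assigned to the untreated samples by replicate number, since the design text has no other control group, and this assignment rests on names only. All values above 0 (100% of them, within 0.01 of a read) were whole multiples of the smallest step of their library. Dividing by that step gave whole reads, 129726756, 156183968, 137964050 and 136134548 in control replicates 1 and 2 and cytoEV replicates 1 and 2. If the authors' counts were estimates rounded to whole numbers, the recovered reads are those rounded estimates. Of the reads, between 17.48% and 20.7% were of Ins1 and Ins2. Of the identifiers, 27 are plain numbers, as spreadsheet software leaves when it turns symbols into dates, and 2 of these occur on 2 rows. They were kept in the tests but are not named.

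Genes with at least 1 CPM in at least 2 of the 4 libraries were tested (12780 genes). The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with an intensity trend in eBayes, the group as the only term, 2 residual degrees of freedom and Benjamini-Hochberg adjustment over all tested genes, with calls at an adjusted p under 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists with at least 5 tested members. They were tested again with an estimated correlation, where camera has only the 2 residual degrees of freedom, and described with fry. Of the 29 lists fixed, 1 had no member in the table and 1 had too few tested members. The test, the lists and the alternatives were fixed before the data were examined. Means are given with the SD over 2 libraries and log2 changes with limma's SE.

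Named genes followed a rule fixed with the design. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM, passing over symbols that are only clone or model numbers. It added up to 3 members with the smallest p in each list (1 or 2 where no member passed), and Cxcl10, Cxcr3, Cxcl9, Cxcl11, Irf1, Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Gcg, Sst and Ppy. Some genes and a list that this rule and the tests covered are not reported here. Genes outside the rule are marked as chosen after their values were seen.

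The same tests were tried with a replicate block, pseudocounts of 0.1, 0.5 and 5, no filter or a filter of 5 CPM, rescaled, quantile-normalized and median-centred values, eBayes without a trend or robust, other thresholds, and each library left out in turn. The count tests edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the recovered reads. Limma with and without the replicate block, both count tests and camera were tried on simulated counts. These had the means and depths of these libraries and 100 genes changed at each fold. The other alternatives and fry were not simulated. Genes were drawn independently, with a dispersion from a set formula, alike in both groups and not estimated from these data. The recovered shares hold for that dispersion only. In the simulated comparison limma recovered 86% of genes changed 2-fold and 16% of those changed 1.5-fold over 12741 tested genes, and 7 of its 126 calls were unchanged genes. In that simulation a list raised 2-fold had a camera adjusted p of 1.06e-66 with the preset correlation, and adjusted p = 0.136 with an estimated correlation. Of 27 unchanged lists 0 were called either way. As the simulated genes were independent, false list calls that correlated genes can cause could not appear there.

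Coordinates and the share of each gene's 50-base stretches that occur in transcripts of other genes were taken from GENCODE M21 (GRCm38, the assembly also called mm10). Of 24419 distinct symbols, 23350 matched GENCODE and 23204 RefSeq on GRCm38.p6. Genes whose RefSeq spans overlap by at least 50% of the smaller span were also summed as an added alternative. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the annotation and the plots.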

Results

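Gene expression was measured by RNA sequencing in isolated pancreatic islets of wild-type C57BL/6 mice. Islets are the clusters of hormone-secreting cells of the pancreas, mostly insulin-producing beta cells with glucagon-producing alpha cells and other endocrine and supporting cells. The 4 libraries form 2 groups of 2. The labels call the control islets untreated. The other group received the treatment the labels call cytoEV every day for 48 h, in medium with 11 mM glucose. A treatment time is given for the cytoEV islets only, so whether control islets were kept as long is not settled here. The series title speaks of small extracellular vesicles, membrane-bound particles that cells release, from pro-inflammatory beta cells and of the chemokine CXCL10 and its receptor CXCR3. In the deposited table the control columns carry a name that reads as control EV, which does not match the label untreated, so whether these islets received vesicles from other cells is not settled here. They are called control islets below. The deposited CPM values (reads scaled to a total of 1000000 per library) were whole multiples of a single read, which gave 129726756 and 156183968 reads in the control libraries and 137964050 and 136134548 reads in the cytoEV libraries. The first principal component of the log2 values held 72.1% of the variance, and both cytoEV libraries lay on the other side of it from both control libraries. No label says whether the 2 islet samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples.

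The comparison of cytoEV islets with control islets asked which transcripts change when islets are exposed to these vesicles. Among the genes named by the fixed rule, the 10 largest rises on the log2(CPM + 1) scale were those of 9 interferon-inducible GTPase genes and of Cxcl10. Iigp1, an immunity-related GTPase, rose from 0.113 ± 0.0148 CPM in control islets to 352.5 ± 13.7 CPM in cytoEV islets (SD, n = 2 each). Lower in the limma test were 10 of 14 glycolysis genes, 12 of 18 hypoxia targets, 10 of 17 immediate early and heat shock genes, 15 of 28 unfolded protein response genes and 7 of 9 acinar markers. With the preset correlation, camera gave these 5 lists, in the same order, adjusted p = 3.3e-12, 1.12e-11, 1.25e-16, 1.19e-13 and 2.73e-11. With an estimated correlation, camera gave adjusted p = 0.153, 0.113, 0.104, 0.113 and 0.113, so none passed that way. Of 12780 genes tested with limma on log2(CPM + 1), 404 were higher and 449 lower in cytoEV islets at a Benjamini-Hochberg adjusted p under 0.05, and 82 of the former and 74 of the latter changed by at least 1 on the log2 scale. The fold changes on this scale understate the change of low genes. In 53.93% of the tested genes the groups did not overlap, against 33.3% by chance with 2 against 2. An exact permutation test of a single gene in this design cannot go below p = 0.333, so each call rests on the spread that limma pools across genes. The counts depended on which libraries set the spread. The 2 control libraries differed more from each other than the 2 cytoEV libraries did. Their chi-square against counting noise, per degree of freedom, was 102.3 for the control pair and 29.32 for the cytoEV pair. Without control replicate 1 limma called 1047 genes higher and 1389 lower, and without control replicate 2 it called 2408 and 2023. Without cytoEV replicate 1 the counts were 215 and 249, and without cytoEV replicate 2 they were 234 and 303. On the recovered whole reads, edgeR called 316 genes higher and 371 lower, and DESeq2 669 and 799. With no filter on low values, limma called 149 and 179, and 19 of the genes named by the rule lost their call, with adjusted p between 0.0515 and 0.122. These were H2-DMb1, H2-Aa, C1ra, Unc13a, Cplx2, Slc7a2, Pyy, Hk1, Tnfrsf1a, Cx3cr1, Cd14, Cd79a, Flt1, Pecam1, Cdh5, Dcn, Col6a3, Spp1 and Cdh19. Where a library was left out, the lone library of its group was assumed to vary like the other group. Calls gained without a control library or lost without a cytoEV library can thus come from the pair that set the spread. They need not mean that a change rests on the library left out.

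**Figure D1:**
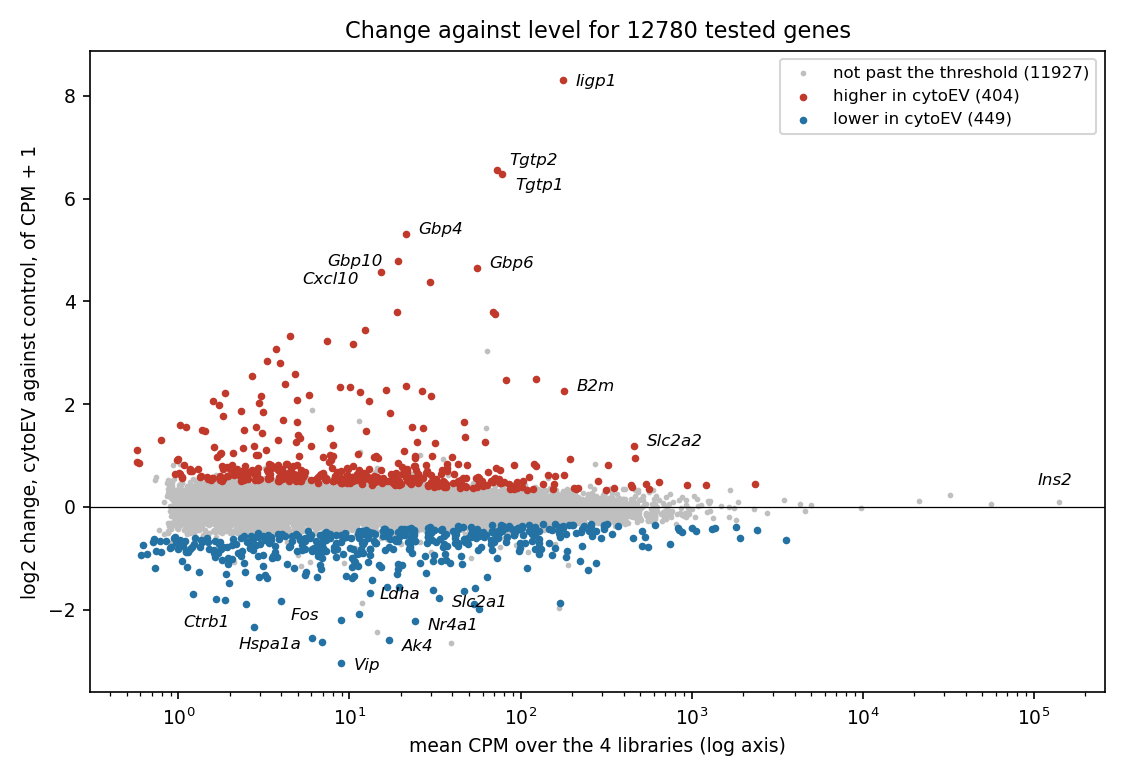
Log2 change of CPM + 1 in cytoEV against control islets (vertical axis) against the mean CPM over the 4 libraries (horizontal log axis) for the 12780 tested genes. Red points are the 404 genes called higher and blue points the 449 called lower by limma, and Iigp1 lies highest, at a log2 change of 8.31.

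Cxcl10, which encodes an interferon-induced chemokine that attracts T cells, was among the 10 largest increases. It lies on chromosome 5 from 92346638 to 92348889 on the minus strand (GRCm38). Its level was 0.314 ± 0.145 CPM in control islets and 30.4 ± 2.1 CPM in cytoEV islets (SD, n = 2 each), a 96.8-fold ratio of the mean CPM. The log2 change was 4.58 ± 0.13 (SE), with a limma adjusted p of 2.42e-07. This size depends on the pseudocount, because the gene was nearly silent in control islets: the log2 change was 2.73 with a pseudocount of 5 and 6.61 in edgeR on recovered reads. Cxcl9, a chemokine that binds the same receptor, had 6 and 0 reads in the control libraries and 267 and 159 reads in the cytoEV libraries (log2 change 1.30 ± 0.17 SE, limma adjusted p = 0.00262). In edgeR its log2 change was 6.12. Cxcl11, the other ligand, is annotated as a polymorphic pseudogene in the reference and stayed below the filter, with 11 and 0 reads in the control libraries and 51 and 41 in the cytoEV libraries. The receptor gene Cxcr3, on chromosome X from 101731535 to 101734269, had 0 and 11 reads in the control libraries and 9 and 6 in the cytoEV libraries, too few to test. At this depth 3 reads correspond to between 0.0192 and 0.0231 CPM. This limit covers counting error only.

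The interferon-inducible GTPases, which act against intracellular pathogens, rose as a group. All 18 members tested were higher, also when adjusted over the list alone, and their median log2 change was 3.78. After Iigp1, whose log2 change was 8.31 ± 0.10 (SE, limma adjusted p = 1.92e-09), the largest rises on the log2(CPM + 1) scale were those of Tgtp2, from 0.542 ± 0.167 to 144.7 ± 3.41 CPM, and Tgtp1, from 0.757 ± 0.188 to 156.1 ± 2.56 CPM (SD, n = 2 each). Their log2 changes were 6.57 ± 0.12 and 6.49 ± 0.12 (SE), each with a limma adjusted p of 1.54e-08. Gbp4, Gbp10, Gbp6, Gbp2, Gbp3 and Irgm2 rose by between 5.30 and 3.79 on the log2(CPM + 1) scale, and Gbp6 reached 108.2 ± 0.851 CPM (SD, n = 2). The order depends on the scale: by the ratio of mean CPM, Gbp4 rose 405.6-fold, Tgtp2 267.1-fold and Tgtp1 206.2-fold. The log2 change of Gbp4 was 8.61 in edgeR, 8.62 in DESeq2 and 3.22 with a pseudocount of 5. Several of these genes are near-identical copies, so their separate values are uncertain. The share of 50-base stretches that also occur in other genes was 81.2% for Tgtp1, 86.6% for Tgtp2, 84.1% for Gbp10 and 70.7% for Gbp6, whereas for Iigp1 the share is 1.7%. The list had a camera adjusted p of 6.31e-48 with the preset correlation of 0.01, and adjusted p = 0.113 with an estimated correlation.

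Of 36 antiviral interferon-stimulated genes tested, 33 rose and 3 did not pass, with a median log2 change of 1.06. Adjusted over the list alone, 35 were higher and 1 lower. Ifit3, an interferon-induced antiviral gene, went from 1.32 ± 0.589 to 19.7 ± 1.19 CPM (SD, n = 2 each). Oasl2, of the oligoadenylate synthetase family, went from 4.95 ± 0.738 to 27.6 ± 1.45 CPM (SD, n = 2 each). Their log2 changes were 3.18 ± 0.17 and 2.27 ± 0.13 (SE), with limma adjusted p of 1.62e-05 and 1.74e-05. Ifit1 rose by 2.06 ± 0.11 on that scale (SE, limma adjusted p = 1.81e-05). Ifit3 shares 51.2% of its 50-base stretches with other genes, mainly Ifit3b. The list's camera adjusted p was 7.62e-36 with the preset correlation, and adjusted p = 0.104 with an estimated correlation.

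MHC class I presentation displays peptides from inside the cell to cytotoxic T cells. Of 23 of its genes tested, 17 rose and 1, the chaperone gene Calr, fell by 0.41 on the log2 scale. Calr was singled out after its values were seen. Adjusted over the list alone, 19 were higher and 2 lower. B2m, the invariant light chain of class I molecules, rose from 62.1 ± 5.50 to 298.2 ± 10.5 CPM (SD, n = 2 each), a log2 change of 2.25 ± 0.09 (SE, limma adjusted p = 2.89e-06). The class I transactivator Nlrc5 rose by 2.33 ± 0.11 and the peptide transporter subunit Tap1 by 2.35 ± 0.12 (SE, limma adjusted p = 7.71e-06 and 8.09e-06). The list had a median of 0.82 and a camera adjusted p of 6e-16, and adjusted p = 0.104 with an estimated correlation. Of 8 MHC class II genes tested, 2 rose, and 3 were higher when adjusted over the list alone. H2-DMb1 changed by 0.53 ± 0.12 and H2-Aa by 0.43 ± 0.10 on the log2 scale (SE, limma adjusted p = 0.0416 and 0.0465). Without cytoEV replicate 1 their adjusted p were 0.0963 and 0.439, and without cytoEV replicate 2 they were 0.188 and 0.457. Those adjusted p were 0.0552 and 0.0556 with quantile normalization, 0.0522 and 0.0593 with median centring, 0.0611 and 0.0602 in edgeR, and 0.0730 and 0.112 with no filter. H2-DMb1 was at 0.0824 in DESeq2 and H2-Aa at 0.0530 with a filter of 5 CPM. The log2 change of H2-DMb1 was 0.834 in edgeR, 0.832 in DESeq2 and 0.213 with a pseudocount of 5. H2-DMb1 shares 22.7% of its 50-base stretches with other genes. EdgeR called 0 of the 8 genes and DESeq2 1. The class II list, with a median of 0.21, had a camera adjusted p of 0.0304, and adjusted p = 0.386 with an estimated correlation. Its preset call was also lost without control replicate 2 (0.31), without cytoEV replicate 1 (0.0589), without cytoEV replicate 2 (0.277) and with a filter of 5 CPM (0.133).

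Other interferon-responsive genes named by the rule were higher too. Cd274, which encodes the T cell inhibitory ligand PD-L1, rose from 22.1 ± 1.92 to 71.3 ± 4.71 CPM (SD, n = 2 each), a log2 change of 1.65 ± 0.10, and the transcription factor gene Irf1 rose by 0.81 ± 0.09 (SE, limma adjusted p = 3.95e-05 and 0.00114).

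NF-kB targets, cytokines and chemokines had 12 members higher and 1 lower among 24 tested, and 16 and 2 when adjusted over the list alone. The NF-kB subunit genes Nfkb2 and Relb rose by 1.47 ± 0.12 and 1.33 ± 0.12 on the log2 scale (SE, limma adjusted p = 0.000221 and 0.000356). Ccl2, a chemokine that attracts monocytes, went from 0.295 ± 0.0900 to 2.59 ± 0.0399 CPM (SD, n = 2 each), a log2 change of 1.47 ± 0.13 in limma (SE, adjusted p = 0.000301) and 3.12 in edgeR. The member that fell was Cebpd, by 1.33, singled out after its value was seen. This list's median was 0.45 and its camera adjusted p 9.89e-07, and adjusted p = 0.191 with an estimated correlation. Of 10 complement components, 3 rose, and 5 were higher and 2 lower when adjusted over the list alone. Cfb, complement factor B, changed by 1.69 ± 0.12 and the inhibitor gene Serping1 by 0.71 ± 0.09 (SE, limma adjusted p = 9.72e-05 and 0.00184). Of the 50-base stretches of Cfb, 73% also lie in other gene models. The third, C1ra, had a limma adjusted p of 0.0466 that became 0.0674 without control replicate 1, 0.171 without cytoEV replicate 1 and 0.0977 without cytoEV replicate 2. It was 0.0531 and 0.0518 with pseudocounts of 0.1 and 5, 0.0592 with quantile normalization, 0.0561 with median centring, 0.0669 in edgeR and 0.0901 in DESeq2. C1ra shares 50.8% of its 50-base stretches with other genes, so its separate value is uncertain. The complement list had a median of 0.29 and a camera adjusted p of 0.0365, and adjusted p = 0.227 with an estimated correlation. Without control replicate 1 its preset adjusted p was 0.127, and without control replicate 2 it was 0.109. It was 0.0669 with quantile normalization and 0.174 with no filter.

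Among genes of apoptosis, pyroptosis and necroptosis, 3 of 29 rose and 2 fell, and 6 and 4 when adjusted over the list alone. Tnfsf10, which encodes the death ligand TRAIL, rose from 8.57 ± 1.19 to 44.8 ± 2.39 CPM (SD, n = 2 each), a log2 change of 2.26 ± 0.12 (SE, limma adjusted p = 1.38e-05). The receptor gene Tnfrsf1a fell by 0.61 ± 0.10 (SE, limma adjusted p = 0.00802), a call that was lost without cytoEV replicate 1 (adjusted p = 0.128). The cell cycle inhibitor gene Cdkn1a, singled out after its value was seen, fell by 0.38. The list as a whole did not pass (median 0.16, camera adjusted p = 0.215).

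Markers of immune cells were measured beside these groups. Among 19 macrophage markers the median log2 change was 0.17 and the list did not pass (camera adjusted p = 0.215). Cx3cr1, a chemokine receptor gene, was higher by 0.75 ± 0.12 and Cd14 lower by 0.62 ± 0.12 (SE, limma adjusted p = 0.00714 and 0.0205). The Cd14 call was lost without cytoEV replicate 1 (adjusted p = 0.0892) and without cytoEV replicate 2 (0.0736). Adjusted over the list alone, 3 macrophage markers were higher and 1 lower. Only 3 of the lymphocyte markers passed the filter, too few for a list test. The B cell gene Cd79a rose from 3.28 ± 0.345 to 5.81 ± 0.359 CPM (SD, n = 2 each), a log2 change of 0.67 ± 0.13 (SE, limma adjusted p = 0.0164) that did not pass without cytoEV replicate 2 (adjusted p = 0.0725). Neither Il7r (adjusted p = 0.0930) nor Lck (0.567) passed, although Il7r passed without control replicate 1 (0.0190), and 1 lymphocyte marker was higher and 1 lower when adjusted over the list alone.

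**Figure D2:**
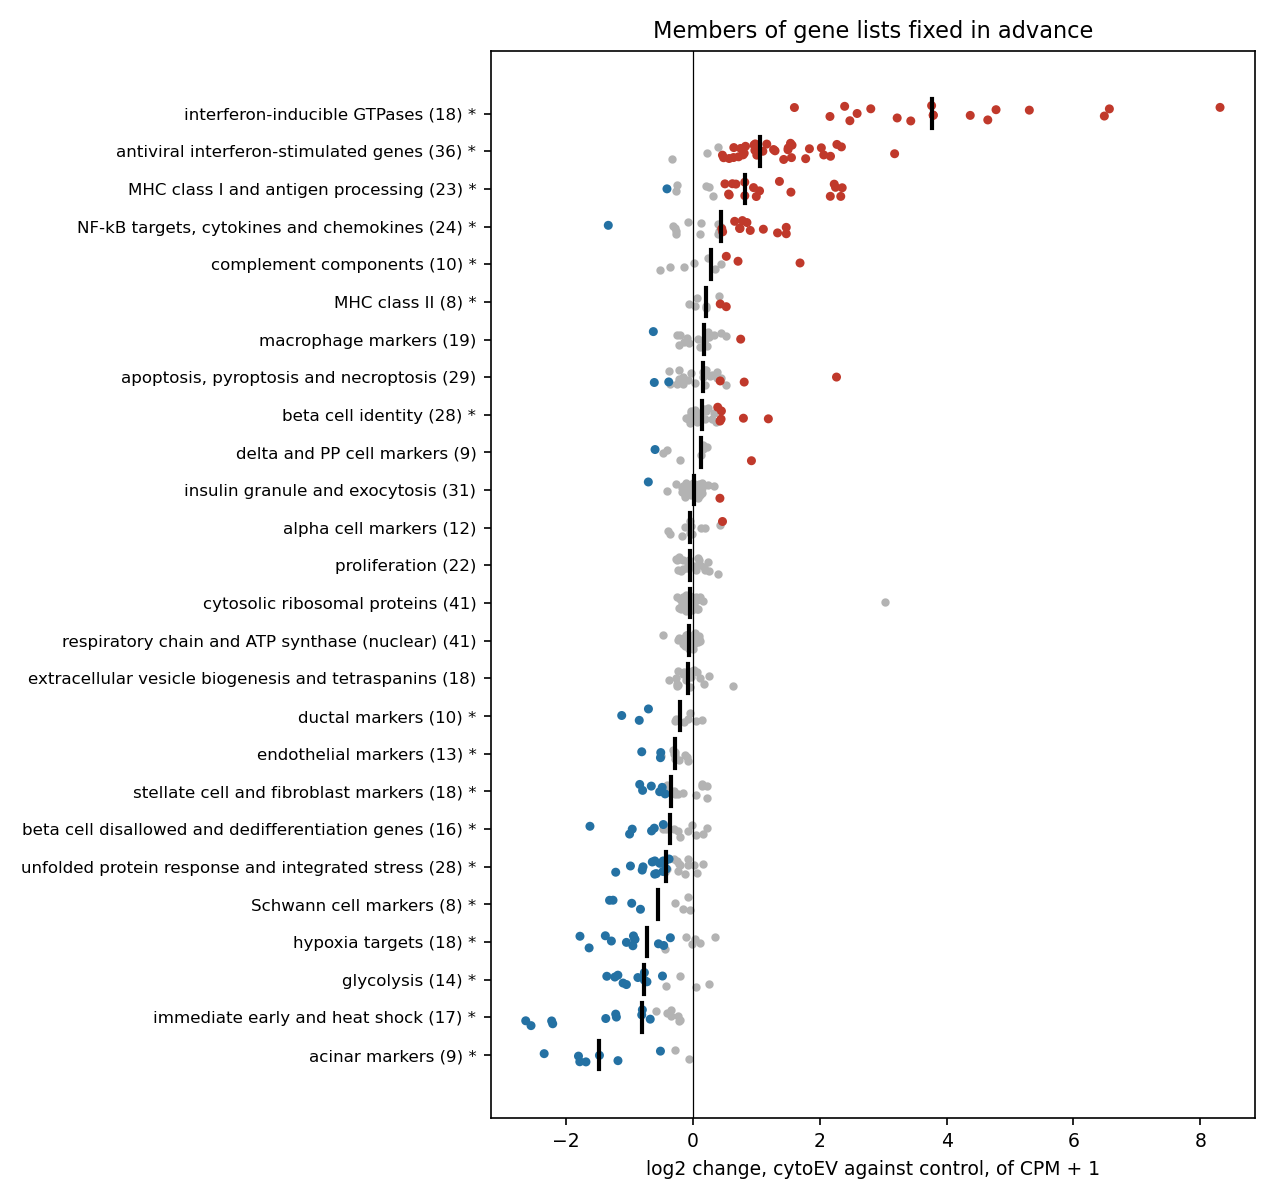
Log2 change of CPM + 1 in cytoEV against control islets (horizontal axis) for each tested member of 26 gene lists fixed in advance (number of members in parentheses). Red and blue points passed the limma test upward and downward, grey points did not, black bars are list medians, and asterisks mark the 17 of them past the camera threshold with the preset correlation. The median was 3.78 for interferon-inducible GTPases and −1.47 for acinar markers.

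Of 28 beta cell identity genes, 6 rose. None was lower: the count was 0 in limma, also at an unadjusted p under 0.05, and 0 in edgeR and DESeq2. Adjusted over the list alone, 9 were higher. Slc2a2, which encodes the glucose transporter GLUT2, rose from 282.1 ± 19.4 to 644 ± 18.6 CPM (SD, n = 2 each), a log2 change of 1.19 ± 0.08 (SE, limma adjusted p = 7.65e-05). The cation channel gene Trpm5 changed by 0.80 ± 0.08 and the incretin receptor gene Glp1r by 0.44 ± 0.08 (SE, limma adjusted p = 0.000936 and 0.0136). The Glp1r call was lost without cytoEV replicate 1 (adjusted p = 0.333) and without cytoEV replicate 2 (0.307). The insulin genes did not pass: Ins1 was at 54999 ± 3458 CPM in control and 57266 ± 2801 CPM in cytoEV islets, and Ins2 at 135487 ± 18679 and 144004 ± 5247 CPM (SD, n = 2 each). Their limma adjusted p were 0.779 and 0.696. The transcription factor genes Pdx1, Mafa and Nkx6-1 had log2 changes of −0.04 ± 0.10, −0.05 ± 0.25 and 0.17 ± 0.10 and the maturity marker Ucn3 0.21 ± 0.08 (SE), and none of these passed. Single libraries turned some of these small changes. Without control replicate 1 those of Pdx1 and Mafa were 0.0503 and 0.38, and Nkx6-1 and Ucn3 passed (adjusted p = 0.0334 and 0.0198). Without control replicate 2 those of Ins1 and Ins2 were −0.0053 and −0.0467, Mafa passed downward at −0.48 (adjusted p = 0.0181), and Ucn3 passed (0.0132). Without cytoEV replicate 1 those of Pdx1 and Mafa were 0.011 and 0.17. With quantile normalization Ucn3 passed (adjusted p = 0.0468). The list had a median of 0.14 and a camera adjusted p of 0.000141, and adjusted p = 0.129 with an estimated correlation. The median log2 changes of acinar, Schwann, stellate, endothelial and ductal cell markers in the same libraries were −1.47, −0.55, −0.35, −0.29 and −0.20.

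Genes of insulin granules and exocytosis showed no shift as a list (median 0.02, mean −0.01, camera adjusted p = 0.95). Of 31 tested, 1 was higher and 1 lower, also when adjusted over the list alone. Unc13a, which encodes a vesicle priming protein, fell from 158.9 ± 18.3 to 96.9 ± 1.76 CPM (SD, n = 2 each), a log2 change of −0.70 ± 0.10 (SE, limma adjusted p = 0.00444). Cplx2, a complexin gene, changed by 0.43 ± 0.08 (SE, limma adjusted p = 0.0185), and this call was lost without cytoEV replicate 1 (adjusted p = 0.309) and without cytoEV replicate 2 (0.427). With quantile normalization the list itself passed upward at an adjusted p of 0.0494. Of 12 alpha cell markers, 1 rose, and 2 were higher and 1 lower when adjusted over the list alone. This was the amino acid transporter gene Slc7a2, with a log2 change of 0.45 ± 0.09 (SE, limma adjusted p = 0.0232), which did not pass without cytoEV replicate 1 (0.401), without cytoEV replicate 2 (0.223) or without the intensity trend (0.0532). The glucagon gene Gcg was at 20577 ± 1014 CPM in control and 22373 ± 200.3 CPM in cytoEV islets (SD, n = 2 each, limma adjusted p = 0.464). The alpha cell list had a camera adjusted p of 0.95. Of 9 delta and PP cell markers, the opioid peptide gene Pdyn rose from 134.5 ± 1.88 to 255.9 ± 0.0456 CPM (SD, n = 2 each), a log2 change of 0.92 ± 0.08 (SE, limma adjusted p = 0.000254). The peptide hormone gene Pyy fell by 0.60 ± 0.12 (SE, limma adjusted p = 0.0199), a call lost without cytoEV replicate 1 (0.172), with quantile normalization (0.0504) and in edgeR (0.0516). Neither the somatostatin gene Sst (adjusted p = 0.294) nor the pancreatic polypeptide gene Ppy (adjusted p = 0.0700) passed, although Ppy passed in DESeq2 (0.00338), without control replicate 1 (0.0104) and without control replicate 2 (5.77e-06), and Sst without control replicate 2 (0.00149). Adjusted over the list alone, 1 delta and PP marker was higher and 3 were lower. That list had a median of 0.12, a mean of −0.01 and a downward camera direction with an adjusted p of 0.95.

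Of 14 glycolysis genes tested, 10 fell, the median log2 change was −0.76, and 11 were lower and 1 higher when adjusted over the list alone. Tpi1, triosephosphate isomerase, fell from 348.5 ± 16.5 to 147.9 ± 0.0544 CPM, and the phosphofructokinase gene Pfkp from 91.8 ± 6.43 to 35.2 ± 0.549 CPM (SD, n = 2 each). Their log2 changes were −1.23 ± 0.08 and −1.36 ± 0.09 (SE, limma adjusted p = 5.11e-05 and 6.51e-05). The list's camera adjusted p was 3.3e-12 with the preset correlation, and adjusted p = 0.153 with an estimated correlation. Hypoxia targets, genes that the hypoxia-inducible factors switch on, were measured beside them: 12 of 18 fell, 13 when adjusted over the list alone, with a median of −0.73. Slc2a1, the glucose transporter GLUT1, went from 52.6 ± 5.90 to 14.6 ± 0.349 CPM and Pfkfb3, an activator of glycolysis, from 70.8 ± 0.307 to 22.2 ± 2.42 CPM (SD, n = 2 each). The log2 changes were −1.78 ± 0.11 and −1.64 ± 0.10 (SE, limma adjusted p = 3.24e-05 and 4.02e-05). Pgk1, a member of both lists, fell by 1.05 ± 0.09 (SE, limma adjusted p = 0.000301), and 53.9% of its 50-base stretches also occur in other genes. The hypoxia list had a camera adjusted p of 1.12e-11, and adjusted p = 0.113 with an estimated correlation. Among the 10 largest decreases were also Ak4, a mitochondrial adenylate kinase gene, by 2.59 ± 0.12, and the transcriptional repressor gene Bhlhe40 by 2.00 ± 0.09 on the log2 scale (SE, limma adjusted p = 7.56e-06 and 6.14e-06). The median log2 changes of acinar, Schwann, stellate, endothelial and ductal cell markers in the same libraries were −1.47, −0.55, −0.35, −0.29 and −0.20.

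Of 16 genes that mature beta cells normally keep low or that mark dedifferentiation, 6 fell, and 8 when adjusted over the list alone. The lactate dehydrogenase gene Ldha fell from 47.1 ± 0.0160 to 14.6 ± 0.0992 CPM (SD, n = 2 each), a log2 change of −1.62 ± 0.10 (SE, limma adjusted p = 2.49e-05). The hexokinase genes Hk1 and Hk2 fell from 14.2 ± 2.21 to 6.58 ± 0.289 CPM and from 4.19 ± 0.0188 to 1.68 ± 0.331 CPM (SD, n = 2 each, limma adjusted p = 0.00311 and 0.00435). These 3 act in glucose metabolism. The list had a median of −0.36 and a camera adjusted p of 1.4e-05, and adjusted p = 0.129 with an estimated correlation. Acinar markers, with a median of −1.47, and Schwann cell markers, with −0.55, were lower in the same libraries. So were stellate, endothelial and ductal cell markers, with medians of −0.35, −0.29 and −0.20.

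Immediate early and heat shock genes respond within minutes to hours to stimulation or protein damage. Of 17 tested, 10 fell, 16 when adjusted over the list alone, with a median of −0.80. Fos dropped from 15.3 ± 1.28 to 2.51 ± 0.0702 CPM, Nr4a1, an orphan nuclear receptor gene, from 40.4 ± 5.93 to 7.81 ± 0.752 CPM, and the inducible heat shock protein gene Hspa1a from 12.7 ± 2.61 to 1.18 ± 0.228 CPM (SD, n = 2 each). Their log2 changes were −2.21 ± 0.12, −2.23 ± 0.13 and −2.64 ± 0.16 (SE, limma adjusted p = 1.58e-05, 2.43e-05 and 2.76e-05). Hspa1b changed by −2.55 ± 0.14 (SE, limma adjusted p = 1.81e-05), and as Hspa1a and Hspa1b are near-identical (60.3% and 62.3% of their 50-base stretches occur elsewhere) their separate values are uncertain. The list's camera adjusted p was 1.25e-16 with the preset correlation, and adjusted p = 0.104 with an estimated correlation. The non-endocrine markers that fell beside this list had medians between −1.47 for acinar and −0.20 for ductal cells. The metallothionein gene Mt2, another of the 10 largest decreases, fell from 84.7 ± 12.7 to 22.1 ± 0.518 CPM (SD, n = 2 each), a log2 change of −1.89 ± 0.12 (SE, limma adjusted p = 3.24e-05).

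Of 28 unfolded protein response and integrated stress genes tested, 15 fell, 21 when adjusted over the list alone, with a median of −0.43. The endoplasmic reticulum stress-induced genes Creld2 and Sdf2l1 fell from 245.8 ± 2.88 to 123.7 ± 4.58 CPM and from 202 ± 5.69 to 115.7 ± 4.13 CPM (SD, n = 2 each). Their log2 changes were −0.98 ± 0.08 and −0.80 ± 0.08, and that of the stress-induced transcription factor gene Atf3 was −1.22 ± 0.13 (SE, limma adjusted p = 0.000207, 0.000789 and 0.00108). The list had a camera adjusted p of 1.19e-13, and adjusted p = 0.113 with an estimated correlation. Beside it, acinar markers had a median of −1.47 and ductal markers one of −0.20.

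Of 9 acinar markers tested, 7 fell, 8 when adjusted over the list alone, with a median of −1.47. Ctrb1, a digestive enzyme precursor, went from 5.32 ± 1.05 to 0.242 ± 0.188 CPM (SD, n = 2 each), a log2 change of −2.34 ± 0.17 (SE, limma adjusted p = 7.52e-05). The trypsinogen genes Try5 and Prss2 fell by 1.80 ± 0.14 and 1.78 ± 0.14 (SE, limma adjusted p = 0.000113 and 0.000152). On the edgeR scale, which adds no pseudocount of 1 CPM, the log2 changes of Ctrb1, Try5 and Prss2 were −4.46, −3.61 and −4.01. Of the 50-base stretches of Try5, 47.6% also occur in other genes. The acinar list had a camera adjusted p of 2.73e-11, and adjusted p = 0.113 with an estimated correlation. Of 8 Schwann cell markers, 4 fell, also when adjusted over the list alone, with a median of −0.55. The glial filament gene Gfap went from 3.13 ± 0.268 to 0.663 ± 0.128 CPM and the neurotrophin receptor gene Ngfr from 8.25 ± 1.56 to 2.84 ± 0.192 CPM (SD, n = 2 each). Their log2 changes were −1.31 ± 0.13 and −1.26 ± 0.14 (SE, limma adjusted p = 0.000683 and 0.00141), and that of Gfap was −2.24 in edgeR. The Schwann cell list had a camera adjusted p of 4.57e-05, and adjusted p = 0.129 with an estimated correlation. Vip, a neuropeptide gene among the 10 largest decreases on the log2(CPM + 1) scale, fell from 16.7 ± 0.629 to 1.14 ± 0.0675 CPM (SD, n = 2 each), a log2 change of −3.04 ± 0.12 (SE, limma adjusted p = 1.90e-06).

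Of 10 ductal markers, 3 fell, and 5 when adjusted over the list alone, with a median of −0.20. Anxa2, an annexin gene that other epithelial cells express too, fell by 1.12 ± 0.11 and the mucin gene Muc1 by 0.85 ± 0.12 on the log2 scale (SE, limma adjusted p = 0.000449 and 0.00467). The ductal list had a camera adjusted p of 0.00108, and adjusted p = 0.153 with an estimated correlation. Of 13 endothelial markers, 3 fell, and 4 when adjusted over the list alone, with a median of −0.29. The vascular growth factor receptor gene Flt1 changed by −0.81 ± 0.12 (SE, limma adjusted p = 0.00481). The calls of Pecam1 and Cdh5 were lost without cytoEV replicate 1 (adjusted p = 0.247 and 0.396) and without cytoEV replicate 2 (0.279 and 0.171), and Cdh5 was at 0.0561 in edgeR. The endothelial list had a camera adjusted p of 0.000123, and adjusted p = 0.153 with an estimated correlation. Of 18 stellate cell and fibroblast markers, 6 fell, and 9 when adjusted over the list alone, with a median of −0.35. The matrix proteoglycan gene Dcn changed by −0.84 ± 0.12 (SE, limma adjusted p = 0.00498). The calls of Fn1 and Col6a3 were lost without cytoEV replicate 1 (adjusted p = 0.241 and 0.293) and without cytoEV replicate 2 (0.269 and 0.108). The stellate list had a camera adjusted p of 0.000134, and adjusted p = 0.153 with an estimated correlation.

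**Figure D3:**
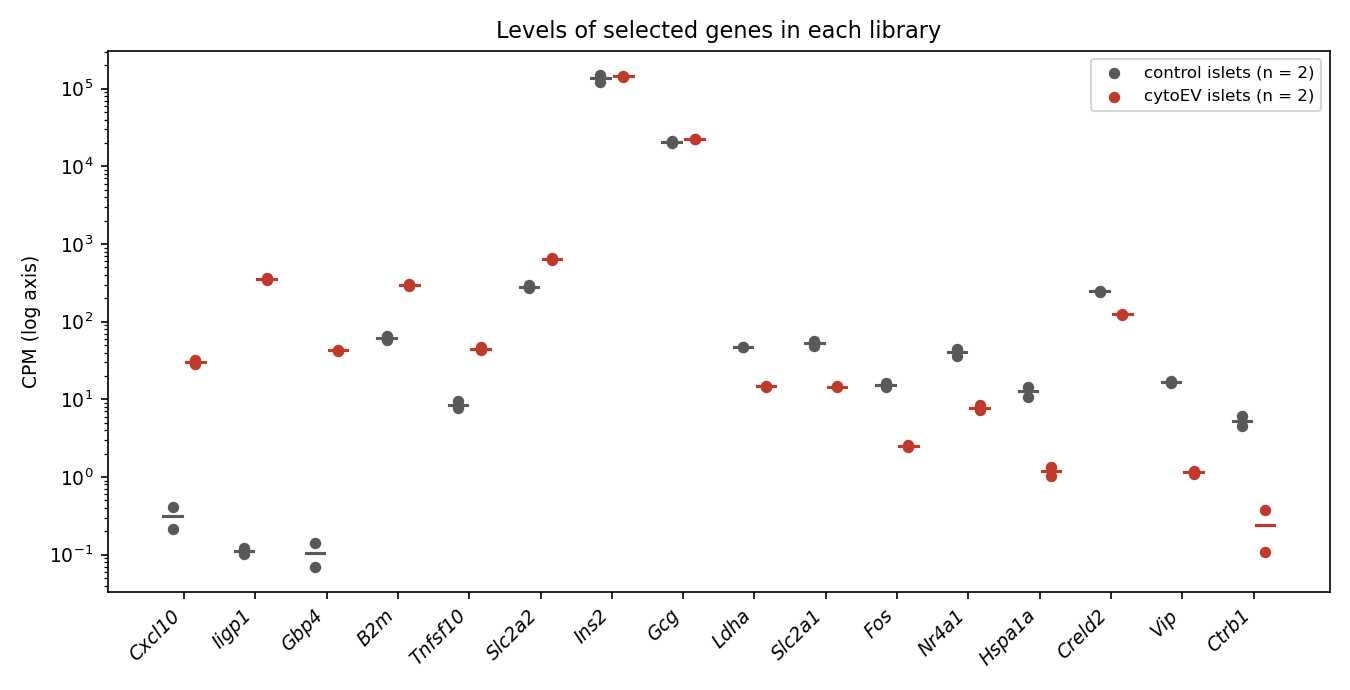
CPM (vertical log axis) of 16 genes named in the text, in each of the 4 libraries (points) with the group mean (bar), grey for control and red for cytoEV islets. Cxcl10 averaged 0.314 CPM in control and 30.4 CPM in cytoEV islets, whereas the 2 groups lay close together for Ins2 and Gcg.

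The remaining lists did not pass in camera. In limma, 0 of 41 nuclear genes of the respiratory chain and ATP synthase passed (median −0.05, camera adjusted p = 0.184), and 1 had an unadjusted p under 0.05. EdgeR called 0 of them and DESeq2 1. Its 2 members with the smallest p, Uqcrq and Cyc1, had limma adjusted p of 0.133 and 0.235, and of 0.00014 and 0.0146 without control replicate 2. Uqcrq passed in DESeq2 (0.0283). Of 41 cytosolic ribosomal protein genes 0 passed in limma, edgeR or DESeq2 and 1 had an unadjusted p under 0.05, with a median of −0.04, a mean of 0.03 and a downward camera direction (adjusted p = 0.203). The sign of the mean came from Rps27, singled out after its values were seen, which had 247.6 CPM in cytoEV replicate 1 and 2.04 CPM in cytoEV replicate 2. Without it the mean of the other 40 genes was −0.05. Its members Rpl38 and Rps2 had limma adjusted p of 0.132 and 0.221. Rpl38 passed without control replicate 1 (0.0162). Without control replicate 2 both genes passed (0.0237 and 0.00143), and so did the ribosomal list, downward (camera adjusted p = 0.0104). Of 22 proliferation genes 0 passed in limma and 3 had an unadjusted p under 0.05, with 0 called by edgeR and 1 by DESeq2 (median −0.04, camera adjusted p = 0.761). The smallest limma adjusted p were those of Cdk1 and Ccnd2, at 0.0934 and 0.101. Cdk1 passed in eBayes without a trend (0.0487), and Ccnd2 without control replicate 1 (0.0249), without control replicate 2 (0.00114), with quantile normalization (0.00983) and in DESeq2 (0.0385). Of 18 genes of extracellular vesicle biogenesis and tetraspanins 0 passed in limma and 5 had an unadjusted p under 0.05, with 0 called by edgeR and 2 by DESeq2 (median −0.07, camera adjusted p = 0.235). The tetraspanin gene Cd81 (log2 change −0.37 ± 0.09 SE, limma adjusted p = 0.0530) passed in DESeq2, with median centring and with robust eBayes (adjusted p = 0.00711, 0.0430 and 0.0459), and without control replicate 1 (0.00909) or control replicate 2 (0.00288). Rab27b had a limma adjusted p of 0.0742, and one of 0.00201 without control replicate 2 and 0.00431 without cytoEV replicate 2. The list of mitochondrially encoded transcripts had no member in the table and was not tested.

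Over the 27 lists tested, 8 were higher and 10 lower with camera's preset correlation. With correlations estimated from the 4 libraries 0 passed, 10 had an unadjusted p under 0.05, and the smallest adjusted p was 0.104. Camera then has only the 2 residual degrees of freedom, so its p can rise without any correlation. For MHC class I the estimated correlation was −0.0016, below the preset 0.01, yet camera p rose from 8.89e-17 to 0.0116. A larger p is therefore by itself no measure of correlation. The preset p assume a correlation of 0.01, whereas the estimate was 0.405 for the interferon-inducible GTPases. It was also higher for glycolysis (0.306), MHC class II (0.271) and NF-kB targets (0.146), so their larger p can in part reflect correlation. For other lists it was lower, such as −0.0314 for immediate early and heat shock genes. In fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, 18 of 28 lists had a directional p under 0.05.

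Clk2-scamp3, another of the 10 largest decreases, is a readthrough gene that spans Clk2 and its neighbour Scamp3. It fell from 19.1 ± 0.979 to 3.76 ± 0.293 CPM (SD, n = 2 each), a log2 change of −2.08 ± 0.12 (SE, limma adjusted p = 1.81e-05). Its reads overlap with those of both neighbours, so its separate value is uncertain. The sum of the 3 genes was 58.2 ± 5.36 CPM in control and 54.5 ± 0.855 CPM in cytoEV islets (SD, n = 2 each).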

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

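Replicate block with crossed pairing and the summing of genes that share a locus were chosen after the results had been seen. Over 20 alternatives Cxcl10 kept its direction and its side of the threshold, with a log2 change between 2.73 (pseudocount of 5) and 6.62 (DESeq2) and a largest adjusted p of 0.00123 (no filter). With no filter on low values 149 genes were higher and 179 lower over 17720 tested, and with a filter of 5 CPM 252 were higher and 302 lower over 10477. At an adjusted p under 0.1 the counts were 804 and 778, and with a log2 change of at least 1 they were 82 and 74, by construction of these thresholds. DESeq2 called 669 genes higher and 799 lower, among which were 384 of the 404 and 444 of the 449. EdgeR called 316 and 371, sharing 301 and 358. A replicate block gave 481 and 512 with 1 residual degree of freedom. With it the MHC class II list (adjusted p = 0.117) and H2-Aa (0.0875) were not called and Ppy (0.0251), Uqcrq (0.0385), Rab27b (0.00138) and the macrophage marker Aif1 (log2 change 0.52, adjusted p = 0.0209) were, and the block with crossed pairing gave 1469 and 1434. The labels do not state that equal numbers mark pairs, and the deviations of same-numbered libraries from their group means had a correlation of −0.22 across genes, which are not independent replicates. Leaving out 1 library gave between 215 and 2408 genes higher, between 249 and 2023 lower, between 6 and 7 lists higher and between 10 and 11 lower. With an estimated correlation, camera called 0 lists higher and 0 lower, against 10 at an unadjusted p under 0.05. In the simulation a list raised 2-fold was also not called that way. Summing genes that share a locus gave 412 and 465. Rescaling to a common total moved nothing, since the columns had that total already. Quantile normalization and median centring moved the median log2 change of all genes from 0.00552 to 0.00178 and −0.0213.

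Of the values of named genes under the alternatives, 1776 kept direction and call, 93 lost the call, 69 gained it and 6 turned, and for lists the numbers were 399, 28, 2 and 0. The log2 change moved by over 1.5 times, with its direction kept, for 28 called named genes with a pseudocount of 5, 7 with a pseudocount of 0.1 and 9 each in edgeR and DESeq2. Each turn was of a gene that had not passed. All alternatives reused the same 4 libraries, so these numbers are no independent support. Among them, rescaling could move nothing, and each changed threshold could only add calls or only remove them. With 1 library left out, Ins1 lay between −0.0053 and 0.12, Ins2 between −0.0467 and 0.24, Pdx1 between −0.12 and 0.0503, and Mafa between −0.48 and 0.38. Apart from the thresholds, the cause was not tested for any of these changes. Depth limits the genes near 0, such as Cxcr3, for which 3 reads are between 0.0192 and 0.0231 CPM.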

Other observations

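The list, bootstrap and locus comparisons in this part were chosen after the results had been seen. So were the gene lists of the next 2 paragraphs, some of whose genes prompted the lists. The limma values of single genes are those of the main test. Genes named here outside the fixed rule were picked after their values were seen. Activity- and CREB-induced genes are switched on by calcium and cyclic AMP signals. Of 20 tested, 5 of which also stand in the lists above, 15 fell, with a median log2 change of −1.01. The kinase gene Sik1 fell from 27.4 ± 1.77 to 10.4 ± 0.000496 CPM and the transcription factor gene Crem from 62.4 ± 6.94 to 28.3 ± 0.404 CPM (SD, n = 2 each, limma adjusted p = 0.000187 and 0.000466). Camera gave an adjusted p of 3.21e-19 over 31 lists, and adjusted p = 0.114 with an estimated correlation. Of 18 sterol synthesis genes 6 fell, with a median of −0.34. Fdps, farnesyl diphosphate synthase, went from 143.4 ± 3.54 to 98.1 ± 3.65 CPM (SD, n = 2 each, limma adjusted p = 0.00655). The sterol list had a camera adjusted p of 3.83e-10, and adjusted p = 0.114 with an estimated correlation. In the same libraries acinar, Schwann, peripheral neuron and stellate cell markers had medians of −1.47, −0.55, −0.50 and −0.35.

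Of 17 markers of peripheral neurons tested, 8 fell, with a median of −0.50 (95% bootstrap interval across genes −0.68 to 0.034). Besides Vip, the microtubule regulator gene Stmn2 fell from 4.49 ± 0.303 to 0.489 ± 0.0872 CPM (SD, n = 2 each, limma adjusted p = 6.26e-05). Th and Elavl4, of the same list, did not pass (log2 change 0.19 and 0.21, limma adjusted p = 0.385 and 0.263). The neuronal list had a camera adjusted p of 1.65e-05, and adjusted p = 0.114 with an estimated correlation. Of 13 metallothioneins and NRF2 targets, which respond to metals and oxidants, 3 fell and 1 rose, with a median of −0.21. The heme oxygenase gene Hmox1 went from 266.9 ± 22.4 to 71.9 ± 1.5 CPM and Nqo1 from 16.4 ± 1.12 to 27.2 ± 1.87 CPM (SD, n = 2 each, limma adjusted p = 7.71e-06 and 0.00676). That list had a camera adjusted p of 3.72e-05, and adjusted p = 0.135 with an estimated correlation.

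Interferon-stimulated genes and GTPases were higher, with a median log2 change of 1.56 over 54 genes (95% bootstrap interval across genes 1.22 to 2.17). More macrophages would raise their markers about as much, but their median over 19 genes was 0.17 (−0.0856 to 0.24), and the abundant markers Lyz2 and C1qa were at 165.7 and 45.4 CPM in control and 142.1 and 61.5 CPM in cytoEV islets. Reads shared between near-identical genes would not raise members with under 5% shared 50-base stretches, and the 34 such members had a median of 1.28 (0.879 to 1.56). Whether the islets transcribed interferon cannot be told apart from interferon that came from outside: 21 interferon genes had 19 reads in all in the cytoEV libraries and 3 in the control libraries, Ifng had 0, and 1 time point leaves an earlier pulse open. A response to the cytoEV treatment remains a hypothesis, a larger number of lymphocytes is left undecided by the 3 markers tested (Cd79a 0.67, Il7r −0.44 and Lck −0.14, of which Cd79a passed), and interferon protein or RNA carried by the vesicles was not tested.

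Hypoxia targets and glycolysis genes were lower, with a median log2 change of −0.76 over 31 genes (95% bootstrap interval across genes −0.94 to −0.45). The intervals of this paragraph resample genes as if independent and leave out the spread between libraries. Fewer cells of another type would lower its markers at least as much, which argues against a loss of macrophages (median 0.17, interval −0.0856 to 0.24) but leaves open a loss of Schwann cells (−0.55, −1.26 to −0.0813), peripheral neurons (−0.50, −0.68 to 0.034), stellate cells (−0.35, −0.46 to −0.0527), endothelial cells (−0.29, −0.50 to −0.22) and ductal cells (−0.20, −0.70 to −0.0442), whose intervals overlap that of the genes to be explained. Acinar markers lost 4.39% of the CPM that the glycolysis genes lost (changes of −82.4 and −1876 CPM), too little for a loss of acinar cells as the whole cause. Dishes that differed in islet density, size or oxygen supply cannot be told apart from the treatment if each group was kept apart: the same genes had a median change of −0.034 between the control libraries and 0.0247 between the cytoEV libraries, and a response to the treatment remains as open.

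The fall of the readthrough gene Clk2-scamp3 may come from reads assigned to another gene of the same locus. The sum of Clk2, Scamp3 and Clk2-scamp3 had a log2 change of −0.0917 ± 0.0938 (SE), while Clk2-scamp3 alone went from 19.1 to 3.76 CPM and Scamp3 from 19.2 to 29.3 CPM. No biological explanation was tested.

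Some pairs of related genes had opposite levels in a single library. Rps27 had 3.22 and 1.67 CPM in the control libraries, 247.6 CPM in cytoEV replicate 1 and 2.04 CPM in cytoEV replicate 2. For Rps27rt the values in the same order were 197.4, 231.1, 12.4 and 227.1 CPM. Their sum was 216.7 ± 22.7 CPM in control and 244.5 ± 21.8 CPM in cytoEV islets (SD, n = 2 each). Nutf2 and Nutf2-ps1 differed in this way in control replicate 2. In the same order, Nutf2 had 6.33, 23.35, 6.705 and 6.62 CPM, and Nutf2-ps1 had 14.62, 0.602, 14.72 and 15.25 CPM. The sum of Nutf2 and Nutf2-ps1 was 22.45 ± 2.12 CPM in control and 21.65 ± 0.313 CPM in cytoEV islets (SD, n = 2 each).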
